A study of Mus musculus with 13 samples.

How the data were processed

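Bulk RNA was sequenced from CD4+ T cells of BDC2.5 NOD mice in 13 libraries, 4 of cells alone, 4 of co-culture with islet macrophages of buffer-treated donors and 5 of co-culture with islet macrophages of STZ-treated donors. Per the labels' protocols, the macrophage donors were injected at 4 weeks of age, islets were taken 10 days later and macrophages were enriched with magnetic beads. RNA was extracted with a column kit for small samples, and cDNA was made from 10 ng of RNA with an integrity score above 8.0 by a template-switching kit that does not keep the strand. Paired-end reads of 150 bases were generated on a NovaSeq, with a target of about 30 M reads per sample, and were aligned to the GRCm38 assembly, per the labels' protocols. The aligner, the counting program and the annotation release are not given in the sources used here. The submitters' processing notes name DESeq2, without a version, and GRCm38.

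The first table holds estimated counts per gene that the authors deposited without normalization. It has 55774 gene entries and 13 columns, each matched to 1 library by the column name the labels give, with 0 columns unmatched. About 11% of the values are not whole, so they are estimates rather than whole reads, and they were rounded for the count tests. Symbols that occur more than once (407 entries) were kept separate. The second table holds log2 values that the authors deposited for 12236 genes. From the values, each is log2 of a whole number plus 1, divided by 1 factor per library. The whole numbers are not the raw counts, so the authors adjusted them beforehand. The table's name points to surrogate variable analysis, and the adjustment itself is not given in the sources used here. This table served only as an alternative, tested with limma on its log2 values.

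Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the group, which left 15781, and libraries were scaled by TMM. The design had 1 term per group and a term for collection day, fitted to all 13 libraries so that they shared 1 estimate of the spread. Quasi-likelihood F tests (robust) were adjusted by Benjamini-Hochberg over the genes of a comparison, and a gene was called at an adjusted p below 0.05. Standard errors are the log2 fold change over the square root of F. The day term rests on the co-cultures, since all cells-alone libraries are of day 1. A model with 1 mean per group and day gave the effect of STZ macrophages within each day and the test of its difference between days; day 2 has 1 control-macrophage library, which is assumed to vary like the other cells. CPM of single genes and summed CPM of the macrophage markers are counts scaled to the library's total times its TMM factor, and log2 CPM used a prior count of 2. The CPM of Malat1, of summed islet endocrine markers and of 3 counts in a single library are scaled to the total alone.

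A gene with no count in the control group of a comparison is given as a bound, with a floor of 3 counts over that group, and a gene with 1 to 3 counts there as a ratio of pooled counts with an exact 95% interval. In single libraries, 3 counts correspond to 0.0490 to 0.173 CPM. The libraries carry no molecular identifiers, so intervals and floors cover counting error only.

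Before the data were examined, 31 gene lists were fixed, for T cell states, cytokines, interferon responses, metabolism, stress, T cell identity and markers of other cells the gate could hold, beside 12 genes given in every comparison. Of the lists, 29 had the 3 tested members that a set test was given. They were tested with limma 3.58.1's camera on voom values (preset correlation 0.01), adjusted over the lists of a comparison, with an estimated correlation and fry as alternatives. The genes named were, per comparison and among called genes with a mean of at least 3 log2 CPM and a symbol that is not a gene model, an immunoglobulin or T cell receptor segment or a mitochondrially encoded gene, the 10 with the largest and the 10 with the smallest log2 fold change. Up to 4 members per described list with the smallest unadjusted p and the 12 fixed genes were added. Of the genes so named, 4 are not reported here. Genes outside this rule are said to be chosen after their values were seen. Of the 25 tested macrophage markers, 18 were under 1 CPM in the cells alone; antigen-presentation members such as Cd74 are also expressed by B cells.

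Replicate numbers are shared between groups. Across genes, the correlation of deviations from the group means was 0.161 to 0.352 in 4 of 4 same-numbered pairs of cells alone and control-macrophage co-culture, so these numbers were taken to pair the libraries from the data; the labels do not state it. Only 2 of 4 correlated best with their own number, and the highest of the pairs with different numbers was 0.433. The pair numbered 3 (r = 0.282) joins a cells-alone library of day 1 with a co-culture of day 2. The pairing is therefore uncertain. Between the STZ-macrophage co-culture and the control-macrophage co-culture it exceeded 0.1 in 3 of 4 pairs, and in 2 of 4 with the cells alone, so there the libraries share only a number. No library pair of a group was a duplicate (smallest chi-square per gene between replicates 26.5).

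The tests were tried on simulated counts drawn from the libraries' means with 200 changed genes. For the comparison of the co-cultures (15426 genes) the edgeR test recovered 6.12% of 2-fold and 34.0% of 4-fold rises, 2.13% of 2-fold and 44.7% of 4-fold falls, and called 1 unchanged gene. With the 9 co-cultures alone (14570 genes) it recovered 32.0% of 2-fold and 62.0% of 4-fold rises and 18.4% and 60.5% of the falls. For the control-macrophage co-culture against the cells alone (15410 genes) 12.0% of 2-fold and 52.0% of 4-fold rises and 6.38% and 36.7% of the falls were recovered, and for the STZ-macrophage co-culture (15421 genes) 6.00%, 32.0%, 2.00% and 30.0%. The Benjamini-Hochberg threshold is stricter with 200 changed genes than where far more genes change. These shares may therefore understate the recovery against the cells alone and in the 9 co-cultures, where many more genes were called. No simulated difference between days was recovered (15395 genes), so that test can miss changes of 4-fold.

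Alternatives fixed beforehand were a minimum absolute log2 fold change of 1, RLE size factors, library sizes, no low-count filter, a filter of CPM of at least 1 in at least 4 libraries, DESeq2 1.42.0 with its Wald test, limma voom, no day term, the libraries of the compared groups only, day 1 only, a replicate block, the second deposited table and leaving out each library in turn. Alternatives chosen after seeing the data were voom with library weights and leaving out STZ-macrophage replicates 2 and 4 or cells-alone replicate 2. Others were the co-cultures alone with a replicate block, without day, of day 1 only, without each library in turn or for the gene lists, the cells-alone axis as a term and offsets corrected for GC content by a loess curve per library. The axis is the first principal component of the 4 cells-alone libraries over 8865 genes with a mean of at least 3 log2 CPM, onto which every library was projected after centring each gene over all libraries. GC content came from the longest transcript of 15361 of 15781 tested genes (97.3%).

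Positions and overlaps came from GENCODE vM21 on GRCm38, the build the labels name; 15372 of the tested symbols (97.4%) were matched, and 17 named genes overlap another gene in more than 10% of their exonic bases. Because the kit does not keep the strand, antisense genes cannot be told apart. Tables were annotated with Python 3.11.15 and pandas 2.3.3, and plots drawn with matplotlib 3.10.9 and numpy 2.4.6. The reads themselves were not analysed here.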

Results

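RNA was sequenced from CD4+ T cells of BDC2.5 mice, a NOD line whose transgenic T cell receptor recognises a beta-cell antigen. Naive splenic T cells of female mice were profiled alone or after 96 hours together with macrophages isolated from NOD islets. The macrophage donors had been given buffer or 1 low dose of streptozotocin (STZ), a toxin taken up by beta cells that kills them. After the co-culture the T cells were sorted as live CD45+Thy1.2+CD4+ cells. There were 4 libraries of cells alone, 4 of T cells with macrophages of buffer-treated donors (control-macrophage co-culture) and 5 of T cells with macrophages of STZ-treated donors (STZ-macrophage co-culture). The labels call the replicates biological and give 2 collection days. Day 1 held all 4 cells-alone, 3 control-macrophage and 2 STZ-macrophage libraries, and day 2 held 1 control-macrophage and 3 STZ-macrophage libraries. The labels do not say whether the cells alone were cultured, so a comparison with them covers culture and macrophages together.

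Total estimated counts were 28.9 M, 17.3 M, 39.8 M and 31.2 M in cells-alone replicates 1 to 4. They were 30.6 M, 61.3 M, 43.5 M and 33.5 M in control-macrophage replicates 1 to 4, and 39.0 M, 58.8 M, 36.7 M, 33.4 M and 35.0 M in STZ-macrophage replicates 1 to 5. Between 15246 and 21014 genes had a count in a library. The first principal component held 56.4% of the variance and placed the cells alone (163 to 200) apart from all 9 co-cultures (-102 to -59.4). The cells alone also differed among themselves. Over 8865 expressed genes, the first principal component of those 4 libraries held 57.0% of their variance, with scores of 66.5, 83.1, -21.5 and -47.8 in replicates 1 to 4. On this axis (called the cells-alone axis here) control-macrophage replicates 1 to 4 scored -8.30, 14.5, -83.6 and -37.5, and STZ-macrophage replicates 1 to 5 scored 53.8, -10.7, -35.3, -16.6 and 43.5.

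**Figure D1:**
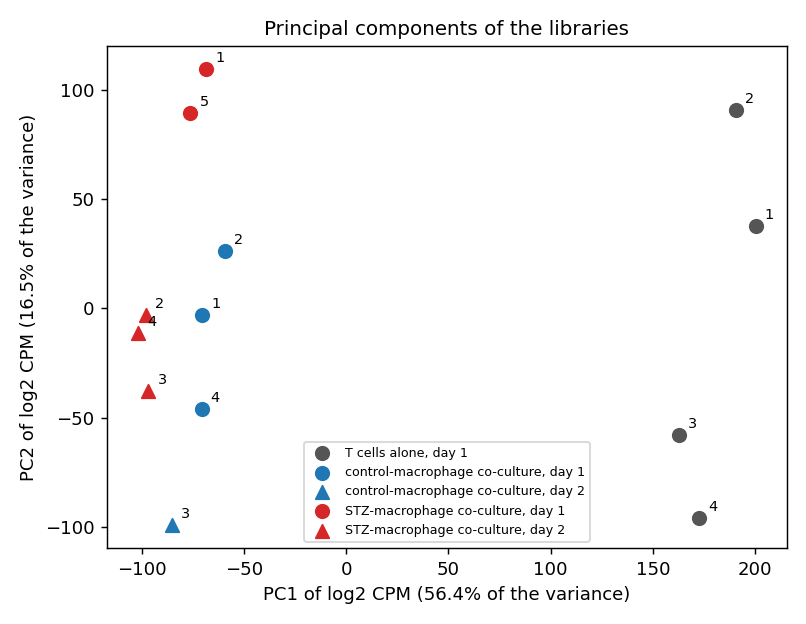
Principal components 1 (56.4% of the variance) and 2 (16.5%) of log2 CPM, 1 point per library, coloured by group, circles for day 1 and triangles for day 2. The 4 cells-alone libraries lie at 163 to 200 on component 1 and the 9 co-cultures at -102 to -59.4; on component 2 STZ-macrophage replicate 1 (109) and control-macrophage replicate 3 (-99.1) are the ends of the co-cultures.

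The first comparison set the STZ-macrophage against the control-macrophage co-culture and asks what macrophages from islets with limited beta-cell death do differently to T cells. T cells of the STZ-macrophage co-culture had more mRNA of the cytokines Il22 and Il17a, of glucose transporters and of glycolytic enzymes. Among genes that were lower, 2 of 18 naive T cell genes and 2 of 36 type I interferon-stimulated genes were called, and these lists passed camera but not with an estimated correlation (adjusted p = 0.136 for both). Il22, a cytokine that acts on epithelial cells, was at 227 ± 163 CPM (SD, n = 5) against 14.99 ± 6.92 (n = 4), a log2 fold change of 4.07 (SE 0.57, adjusted p = 0.0312). Il17a, the defining cytokine of T helper 17 cells, was at 8.46 ± 1.49 against 0.548 ± 0.419 CPM (log2 fold change 3.89, SE 0.55, adjusted p = 0.0312). Of 15781 genes tested, 24 rose and 27 fell (edgeR quasi-likelihood test with collection day as a term, Benjamini-Hochberg adjusted p under 0.05), and 3604 had an unadjusted p under 0.05 (1261 higher, 2343 lower). The balance of those depended on the scaling, with 1797 higher and 1263 lower by RLE, 1832 and 1071 by library sizes and 2382 and 1498 by DESeq2.

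Among called genes with a mean of at least 3 log2 CPM, beside Il22, the largest rises were in Furin, a protease that activates secreted precursors (log2 fold change 3.40), and Tnfrsf8, the receptor CD30 (2.41). Furin stood at 103 and 83.1 CPM in STZ-macrophage replicates 1 and 5 of day 1, and at 4.07 to 5.33 in replicates 2 to 4 of day 2. The control-macrophage co-culture was at 3.24 to 4.70 on day 1 and at 1.48 in its only day 2 library. Next came Ier3, an immediate-early gene, at 21.7 ± 3.22 against 4.74 ± 0.480 CPM (2.30, SE 0.27, adjusted p = 0.00870), Hk2 (2.17), the Toll-like receptor adaptor Tirap (2.14) and Slc2a3 (1.95). Ndrg1, a gene induced by low oxygen and linked to T cell anergy (1.95), Mxi1, an antagonist of MYC (1.84), and Gatm, an enzyme of creatine synthesis (1.84), rose as well. Under the same limit, and leaving out gene models and immunoglobulin and T cell receptor genes, the largest falls were in Nacc2 (log2 fold change -2.56, SE 0.28, adjusted p = 0.00870), Dapl1 (-2.29), Cpne4 (-1.88), the tetraspanin Tspan32 (-1.86, SE 0.23, adjusted p = 0.00933) and Il6ra, the interleukin 6 receptor (-1.78). Cd7 (-1.72), Slamf6 (-1.65), Arl5c (-1.65), Pecam1 (-1.63) and Emp3 (-1.55) followed, Tspan32 at 48.8 ± 5.83 against 195 ± 39.9 CPM and Slamf6 at 70.8 ± 9.05 against 209 ± 33.3 CPM. All adjusted p of these genes were between 0.00870 and 0.04998 by the edgeR test. In the annotation (GENCODE vM21 on GRCm38) Il22 is on chromosome 10 at 118204942 to 118210047 on the plus strand, and its near-identical copy Iltifb at 118289629 to 118295038 on the minus strand. Iltifb, named after its values were seen, was also called (4.35), so the split of reads between the copies is uncertain. Nacc2 (chromosome 2, 26055535 to 26123220) has 6.10% of its exonic bases under the antisense gene Gm13554, and reads of the pair cannot be separated in an unstranded library.

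**Figure D2:**
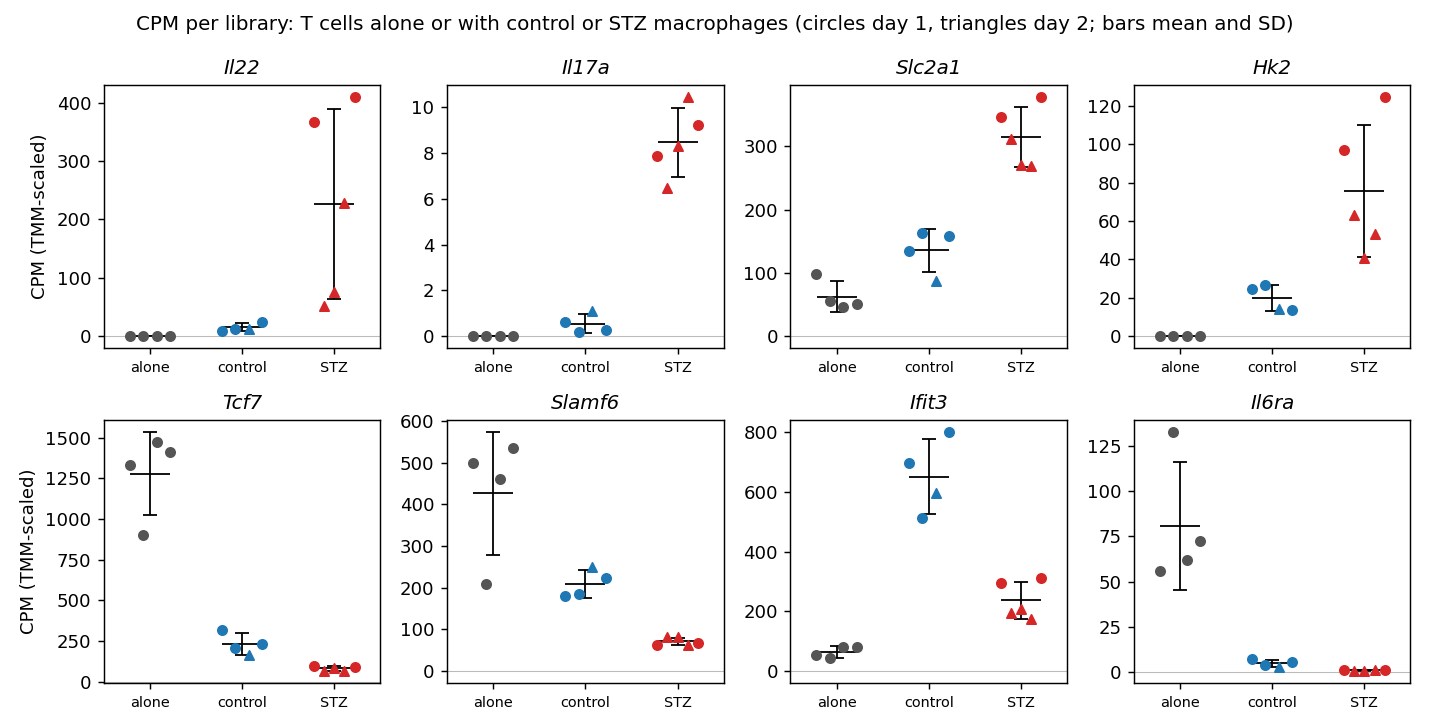
CPM on a linear axis for Il22, Il17a, Slc2a1, Hk2, Tcf7, Slamf6, Ifit3 and Il6ra in every library, by group, with circles for day 1, triangles for day 2 and bars for the mean and SD. Il22 averaged 227 CPM in the STZ-macrophage co-culture (n = 5), 14.99 in the control-macrophage co-culture (n = 4) and 0 in the cells alone (n = 4), whereas Tcf7 averaged 81.6, 231 and 1279 CPM.

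Glycolysis was the gene group with the firmest difference. Of 20 glycolysis genes measured, 4 rose and none fell over all genes tested (19 had a positive log2 fold change), and 10 rose when adjusted over the list alone. Hk2, which traps glucose in the cell, was at 75.9 ± 34.5 against 19.7 ± 6.84 CPM (log2 fold change 2.17, SE 0.32, adjusted p = 0.0199 by edgeR). The glucose transporter Slc2a3 was at 247 ± 158 against 71.3 ± 9.58 CPM (1.95, SE 0.29), the transporter Slc2a1 at 315 ± 47.9 against 136 ± 34.4 CPM (1.42, SE 0.24), and the aldolase Aldoa at 2861 ± 292 against 1655 ± 47.8 CPM (0.82, SE 0.14). Hk2 lies on chromosome 6 at 82725025 to 82774454, Slc2a3 on chromosome 6 at 122727809 to 122801640 and Slc2a1 on chromosome 4 at 119108711 to 119137983. The list was higher by camera (adjusted p = 9.6e-12) and stayed so with an estimated correlation (adjusted p = 0.00616), the only list of this comparison that did. With the cells-alone axis as a term the adjusted p with an estimated correlation was 0.00983, and after a correction for GC content it was 0.198. That correction left the list higher by camera with the preset correlation (adjusted p = 1.6e-06), with a median log2 fold change of 0.72 against 1.12 before. Hk2 (2.01) and Slc2a3 (1.98) stayed called, while Slc2a1 (1.09, adjusted p = 0.0697) and Aldoa (0.13, adjusted p = 0.793) did not.

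T helper 17 genes and cytokines passed camera as higher, but not with an estimated correlation (adjusted p = 0.136 and 0.110). Of 11 T helper 17 genes, Il22 and Il17a rose, and 6 did when adjusted over the list alone. Il17f stood at 101 ± 37.8 against 22.8 ± 12.2 CPM (log2 fold change 2.12, edgeR adjusted p = 0.0996) and the interleukin 1 receptor Il1r1 at 5.97 ± 2.92 against 1.30 ± 0.520 CPM (2.42, adjusted p = 0.0702). The camera test gave an adjusted p of 3.4e-06 for the T helper 17 list, and an adjusted p = 0.136 with an estimated correlation. Of 28 cytokine and chemokine genes, the same 2 rose (adjusted over the list alone, 6 rose and 1 fell), with a camera adjusted p of 6.4e-04 and an adjusted p = 0.110 with an estimated correlation. Ccl22, a chemokine outside that rule and named after its values were seen, had a log2 fold change of 3.16 and was called. With the cells-alone axis as a term, the lists' adjusted p with an estimated correlation were 0.0932 for T helper 17 genes and 0.106 for cytokines.

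Interferon-stimulated genes passed camera as lower, but not with an estimated correlation (adjusted p = 0.136 for type I and 0.387 for gamma). Of 36 type I interferon-stimulated genes, 2 fell over all genes tested and 27 fell when adjusted over the list alone, and 3 had a positive log2 fold change. Ifit3, an antiviral effector, was at 237 ± 62.5 against 652 ± 126 CPM (log2 fold change -1.34, SE 0.22, edgeR adjusted p = 0.0341), and Ifit1 at 197 ± 27.4 against 396 ± 61.5 CPM (-0.90, SE 0.17, adjusted p = 0.0471). Ifi203 (-1.24, adjusted p = 0.0602) and Ifi27l2a (-0.94, adjusted p = 0.0665) did not pass the edgeR test. The list had a camera adjusted p of 5.8e-14 and an adjusted p = 0.136 with an estimated correlation. The 23 genes of the interferon gamma response, with Irgm2 (-1.02) and Irgm1 (-0.89) among those with the smallest p, had none called over all genes by edgeR and 12 lower when adjusted over the list alone. Their camera adjusted p was 0.00198, with an adjusted p = 0.387 with an estimated correlation. With the cells-alone axis as a term, the adjusted p with an estimated correlation were 0.106 for the type I list and 0.352 for the gamma list.

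Genes of naive and follicular helper T cells passed camera as lower too, but not with an estimated correlation (adjusted p = 0.136 and 0.0809). Of 18 naive and quiescence genes, Dapl1 and Tcf7 fell over all genes tested, and 8 fell when adjusted over the list alone. Tcf7, the transcription factor TCF-1 of naive and memory T cells, was at 81.6 ± 14.2 against 231 ± 66.2 CPM (log2 fold change -1.32, SE 0.20, edgeR adjusted p = 0.0199), and Dapl1 at 44.6 ± 22.9 against 148 ± 42.5 CPM. The antiproliferative gene Btg2 (-1.02, edgeR adjusted p = 0.0585) did not pass. Of 12 follicular helper genes, Tcf7, Slamf6 and Il6ra fell (5 adjusted over the list alone). Camera gave an adjusted p of 0.00129 for the naive list (adjusted p = 0.136 with an estimated correlation) and 0.00198 for the follicular helper list (adjusted p = 0.0809 with an estimated correlation). The 18 T cell identity genes were lower (camera adjusted p = 5.9e-04; adjusted p = 0.319 with an estimated correlation) with none called over all genes by edgeR, but 12 lower and 1 higher adjusted over the list alone. Among them the costimulatory receptor Cd27 was at -1.11 (adjusted p = 0.0565) and the co-receptor Cd4 at 895 ± 100 against 1121 ± 83.0 CPM (-0.41, adjusted p = 0.182). Homing and chemokine receptors were lower (17 genes, none called by edgeR, 3 adjusted over the list alone; camera adjusted p = 0.0431, and adjusted p = 0.136 with an estimated correlation), and with the cells-alone axis as a term that list's adjusted p was 0.112.

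Stress-related groups were higher by camera with few or no called members. The first was the list of integrated stress response and serine genes (21 genes, none called by edgeR or adjusted over the list alone; camera adjusted p = 0.00248, and adjusted p = 0.0731 with an estimated correlation). The other was that of p53 targets (17 genes, none called, 1 adjusted over the list alone; camera adjusted p = 0.00694, and adjusted p = 0.197 with an estimated correlation). The immediate-early and heat shock genes, a list set up for sorting stress, had Ier3 called among 13 (2 higher and 1 lower adjusted over the list alone). Their camera adjusted p was 0.00694, and 0.136 with an estimated correlation. Asns, the asparagine synthase, was at 60.4 ± 9.49 against 28.6 ± 10.8 CPM (edgeR adjusted p = 0.131) and the p53 regulator Mdm2 at 99.6 ± 46.6 against 37.8 ± 10.8 CPM (adjusted p = 0.131). With the cells-alone axis as a term the p53 list had an adjusted p of 0.350. That term took the median log2 fold change of the immediate-early and heat shock list from 1.02 to 0.04. Its camera adjusted p was then 0.0349, and 0.230 with an estimated correlation.

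Other groups did not pass camera. Adjusted p were 0.471 for activation, 0.420 for the cell cycle, 0.294 for T helper 1 and cytotoxic genes, 0.471 for T helper 2, 0.670 for regulatory T cell, 0.949 for inhibitory receptor, 0.388 for anergy, 0.186 for oxidative phosphorylation, 0.497 for cholesterol, 0.471 for ribosome biogenesis and 0.717 for transforming growth factor beta response genes. Members of these lists went both ways, and median, mean and test direction differed in sign for the T helper 2, cell cycle, inhibitory receptor, oxidative phosphorylation, cholesterol and transforming growth factor beta lists. Il2ra, the interleukin 2 receptor of activated T cells, was at 2010 ± 539 against 2051 ± 903 CPM and the proliferation marker Mki67 at 320 ± 73.3 against 441 ± 90.7 CPM. Foxp3, the regulatory T cell factor, was at 12.5 ± 6.77 against 58.9 ± 37.7 CPM (log2 fold change -2.51, SE 0.84, edgeR adjusted p = 0.160), and Ifng at 63.0 ± 37.3 against 19.4 ± 21.95 CPM (1.15, adjusted p = 0.230). Of the remaining genes set beforehand, Cd44 was at -0.64 (adjusted p = 0.115), Tbx21 at 1.39 (0.450), Pdcd1 at -0.85 (0.216), Izumo1r at -0.95 (0.235) and Nt5e at 1.41 (0.189). Lag3 had too few counts to be tested.

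**Figure D3:**
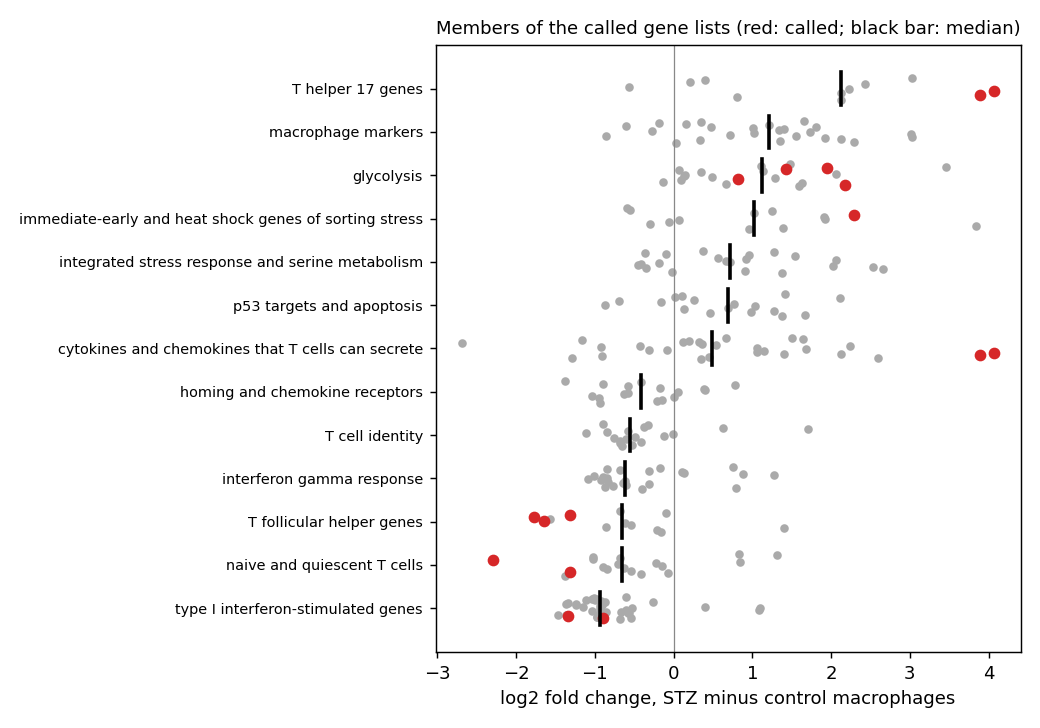
Log2 fold change, STZ-macrophage over control-macrophage co-culture, of every tested member of the 13 gene lists that passed camera, 1 point per gene, red where the gene itself was called, with a black bar at the list median. The glycolysis members have a median of 1.12 with 19 of 20 above 0, and the type I interferon members a median of -0.94 with 3 of 36 above 0.

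Transcripts of other cell types were compared as well. Of 25 macrophage markers, 21 had a positive log2 fold change, none was called by edgeR or adjusted over the list alone, and the list was higher by camera (adjusted p = 0.00608), with an adjusted p = 0.539 with an estimated correlation. The complement gene C1qc was at 3.21 ± 2.27 against 0.278 ± 0.146 CPM (adjusted p = 0.160) and the receptor Csf1r at 3.00 ± 2.08 against 0.442 ± 0.308 CPM (adjusted p = 0.159), while the lysosomal protease Ctss was at 220 ± 38.8 against 353 ± 120 CPM. Islet endocrine markers summed to 149 and 141 CPM in STZ-macrophage replicates 2 and 4, both of day 2, and to at most 4.71 CPM in each other library. Ins2, an insulin gene, was at 8.78 ± 14.9 CPM in the STZ-macrophage co-culture and had so few counts in the control-macrophage co-culture that its ratio was 832 (exact 95% interval 230 to 6878; edgeR adjusted p = 0.0713). Ighm, the immunoglobulin mu chain, was lower (169 ± 19.1 against 679 ± 81.4 CPM; log2 fold change -1.99, adjusted p = 0.00870), the only B cell marker of 10 called, with Cd79a at 0.528 ± 0.150 against 0.799 ± 0.416 CPM. Pecam1 was the only called one of 4 stromal and endothelial markers. Camera adjusted p were 0.756 for B cell, 0.635 for CD8 and NK cell, 0.416 for endocrine and 0.825 for stromal markers, and 0.353 for the 13 mitochondrially encoded transcripts. The acinar marker Cela1 (0.45, edgeR adjusted p = 0.739) and the erythroid gene Hba-a1 (0.76, adjusted p = 0.746) were the only tested members of their lists.

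Within day 1, 27 genes were higher and 7 lower in the STZ-macrophage co-culture, and within day 2, with 1 control-macrophage library, none was called by edgeR although 2212 had an unadjusted p under 0.05. All 51 genes had the same sign on both days, although the libraries of both days had been used to pick them. Il22 had a log2 fold change of 4.62 on day 1 and 3.25 on day 2. The difference between the days was called for 1 gene, Arrb1, a regulator of receptor signalling named after its values were seen, at 3.90 on day 1 and -0.39 on day 2 (difference -4.28, SE 0.48, edgeR adjusted p = 0.0249). A total of 1549 genes had an unadjusted p under 0.05 for that difference, and DESeq2 called 404.

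The count of 51 depended on which libraries shared the fit. Among the 9 co-cultures alone, edgeR called 1498 genes higher and 1200 lower, the 51 with the same sign among them. DESeq2 called 650 and limma voom 508 with all 13 libraries, and leaving out cells-alone replicate 2 gave 582, replicate 4 gave 99, replicate 1 gave 79 and replicate 3 gave 42. Without control-macrophage replicate 1, 2, 3 or 4 the count was 4, 6, 87 and 0, and without STZ-macrophage replicate 1, 2, 3, 4 or 5 it was 0, 8, 24, 5 and 0. The edgeR counts of 0 came with 1555, 2061 and 2522 genes at an unadjusted p under 0.05 (without control-macrophage replicate 4 and STZ-macrophage replicates 1 and 5). Without STZ-macrophage replicates 2 and 4, the libraries with islet transcripts, none was called either (1820 unadjusted); other tools were not run on these subsets. RLE size factors called 30 higher and 14 lower, and scaling by library size 38 and 19. The median log2 fold change of all genes was -0.13 with TMM, -0.03 with RLE and 0.07 with library sizes. Across genes, which are not independent replicates, the log2 fold changes correlated with the loadings of the cells-alone axis (r = 0.778). With the axis as a term 6 genes were called, 5 of them among the 51 (Tspan32, Ier3, Nacc2, Ccnd3 and Ighm), and all 51 kept their sign.

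The second comparison set the control-macrophage co-culture against the cells alone and describes T cells that had met islet macrophages. These T cells had more mRNA of the interleukin 2 receptor and of cell division, cytokine and glycolysis genes, and had less mRNA of receptors and factors of naive T cells. Il2ra, not counted in any cells-alone library, was at 2051 ± 903 CPM (n = 4), at least 91562-fold higher (floor of 3 counts over the group). The mitotic kinase Bub1 was at 376 ± 108 CPM against 0 (at least 16787-fold), and Mki67 at 441 ± 90.7 against 0.836 ± 0.732 CPM (log2 fold change 8.93, SE 0.78, edgeR adjusted p = 2.6e-06). Il7r, the interleukin 7 receptor that keeps naive T cells alive, fell from 2932 ± 1040.3 to 231 ± 64.9 CPM (-3.74, SE 0.29). Of 15781 genes, 3641 rose and 3465 fell by edgeR, and 8305 had an unadjusted p under 0.05. Scaled by library size the split was 2912 higher and 4639 lower, and the median log2 fold change of all genes was -0.13 with TMM, -0.08 with RLE and -0.45 with library sizes.

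Cell cycle and activation genes rose. Of 33 genes of DNA replication and mitosis, 32 rose and none fell, over all genes and adjusted over the list alone, with Birc5 at 825 ± 110 against 0.329 ± 0.225 CPM (log2 fold change 11.21, SE 0.45), and Tk1 (6.62) among them (camera adjusted p = 1.3e-19, and adjusted p = 0.00408 with an estimated correlation). Of 19 activation genes 15 rose (15 and 1 lower adjusted over the list alone), among them the costimulatory receptors Tnfrsf9 (9.06) and Tnfrsf4 (6.13) and the adhesion receptor Cd44 (2.61; camera adjusted p = 1.4e-07, and adjusted p = 0.0211 with an estimated correlation). The division genes Kif18b (at least 8673-fold), Pbk (6891), Neil3 (4234) and Pimreg (4220), the cytokine Lif (6187) and the leucine-degrading enzyme Bcat1 (5456) had a count of 0 in the cells alone. Hmmr was at 570 ± 180 CPM and Ifitm3, an interferon-induced antiviral gene, at 594 ± 83.3 CPM, with ratios of 23961 (exact 95% interval 8199 to 116192) and 38222 (10581 to 315614).

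Most genes of the cytokine and regulatory T cell lists rose. Of 28 cytokine genes 22 rose and 1 fell (the same counts adjusted over the list alone; camera adjusted p = 1.4e-07, and adjusted p = 0.0168 with an estimated correlation), with Lta at 547 ± 234 against 14.9 ± 4.31 CPM and Il24 at least 961-fold higher. The median log2 fold change of the list was 6.80, and 5.35 with the 15 genes at 0 in the cells alone set at their bound. Of 23 T helper 1 and cytotoxic genes 15 rose and 1 fell (16 and 2 adjusted over the list alone), with the protease Gzmb at 2196 ± 2089 against 0.185 ± 0.351 CPM, Nkg7 (6.75), Il12rb2 (9.39) and Id2 (2.55; camera adjusted p = 1.8e-05, and adjusted p = 0.242 with an estimated correlation). Of 11 T helper 17 genes 8 rose (8 adjusted over the list alone), with Il17f at least 1018-fold, Il22 at least 669-fold, Ccr6 at least 61.5-fold and Il1r1 at least 58.1-fold higher (camera adjusted p = 0.00280, and adjusted p = 0.246 with an estimated correlation). Of 18 regulatory T cell genes 16 rose (16 adjusted over the list alone), with Foxp3 at 58.9 ± 37.7 against 1.52 ± 0.690 CPM (5.26), Capg (6.05) and Entpd1 (4.39; camera adjusted p = 4.5e-08, and adjusted p = 0.00408 with an estimated correlation). Of 18 inhibitory receptor and exhaustion genes 12 rose and 3 fell (12 and 4 adjusted over the list alone), with Havcr2 (6.65) and Ctla4 (6.52) higher and the transcription factor Tox lower (-2.06; camera adjusted p = 0.0225, and adjusted p = 0.342 with an estimated correlation). Il12rb2 overlaps the antisense gene Serbp1 in 40.04% of its exonic bases and Foxp3 overlaps Flicr in 18.6%, so their counts are uncertain. Gbp6 (29.0%), Ifng (25.9%) and Lilrb4a (35.3%) overlap gene models on their own strand and share this limit.

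Most genes of the interferon, glycolysis, oxidative phosphorylation and cholesterol lists rose too. Of 36 type I interferon-stimulated genes 30 rose and none fell (31 adjusted over the list alone), with Ifi27l2a at 2783 ± 511 against 63.2 ± 12.2 CPM (log2 fold change 5.56, SE 0.24), Isg15 (5.55), Ifit1 (3.96) and the regulator Irf7 (3.17; camera adjusted p = 6.7e-16, and adjusted p = 0.0802 with an estimated correlation). Of 23 interferon gamma response genes 19 rose (19 adjusted over the list alone), with Gbp6 (4.29) among them (camera adjusted p = 8.1e-10, and adjusted p = 0.0660 with an estimated correlation). Of 20 glycolysis genes 15 rose (16 adjusted over the list alone), with Tpi1 (5.12), Gapdh (3.28) and Ldha (2.82; camera adjusted p = 5.1e-08, and adjusted p = 0.0173 with an estimated correlation). These 3 genes have processed pseudogenes that could share reads. Of 45 oxidative phosphorylation genes 30 rose (32 adjusted over the list alone), among them Cycs (1.77) and Ndufs8 (1.64; camera adjusted p = 7.6e-08, and adjusted p = 0.0669 with an estimated correlation). Of 24 cholesterol genes 16 rose (17 adjusted over the list alone), with Idi1 (2.89) and Mvd (2.25; camera adjusted p = 2.8e-05, and adjusted p = 0.0772 with an estimated correlation). Of 21 integrated stress response and serine genes 10 rose and 2 fell (11 and 2 adjusted over the list alone), with Asns at least 1275-fold, Psat1 (4.75) and Phgdh (3.05) higher (camera adjusted p = 0.00280, and adjusted p = 0.0310 with an estimated correlation).

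Naive genes and transforming growth factor beta response genes fell. Of 18 naive and quiescence genes 15 fell and 2 rose (the same adjusted over the list alone), with Il7r, Klf3 (-3.09), S1pr1, the receptor for exit from lymphoid organs (-2.47), and Tcf7 (-2.37) lower (camera adjusted p = 2.3e-06, and adjusted p = 0.0325 with an estimated correlation). Of 12 transforming growth factor beta response genes 7 fell and 2 rose (8 and 2 adjusted over the list alone), with the feedback inhibitors Tgif1 (-3.57) and Skil (-2.48) among those lower (camera adjusted p = 7.7e-04, and adjusted p = 0.0435 with an estimated correlation). Among the largest falls were St8sia6 (192 ± 33.5 to 0.648 ± 0.386 CPM, log2 fold change -8.58), Patl2 (-8.20), H2-Ob (-7.23), Prg4 (-6.89), the growth factor receptor Igf1r (-6.83), Rflnb (-6.02), Pstpip2 (-5.83), Pou6f1 (-5.54) and Tdrp (-5.38).

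Groups that did not pass camera were T helper 2 (adjusted p = 0.225), follicular helper (0.987), anergy (0.629), ribosome biogenesis (0.155), p53 targets (0.53), trafficking (0.53), immediate-early genes (0.635) and T cell identity (0.53). The follicular helper, anergy and immediate-early lists had a median, mean and test direction that differed in sign. Macrophage markers had 7 of 25 higher and none lower (7 adjusted over the list alone; camera adjusted p = 0.0866), with Lyz2 at 7.61 ± 11.5 against 0.0366 ± 0.0732 CPM and C1qb (3.44) called. B cell (0.53), CD8 and NK cell (0.53), endocrine (0.764) and stromal markers (0.53) and mitochondrially encoded transcripts (0.124) did not pass, and neither did Cela1 (edgeR adjusted p = 0.321) or Hba-a1 (0.698). The cytotoxic protease Gzma (4.52) and Cd4 (0.59, adjusted p = 0.0108) rose, and Ighm (-0.88) fell. Of the remaining genes set beforehand, Ifng was at least 864-fold higher, Pdcd1 (2.57) and Izumo1r (2.91) rose, and Tbx21 (2.75, adjusted p = 0.120) and Nt5e (-0.64, adjusted p = 0.398) did not pass. The cells alone were also further from each other than the co-cultures were, with a median SD of log2 CPM of 0.703 against 0.404. The RNA Malat1, named after its values were seen, stood at 3124 to 8104 CPM in them against 315 to 631 CPM in the co-cultures.

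The third comparison set the STZ-macrophage co-culture against the cells alone. Il22 and Il17f had larger bounds here than in the control-macrophage co-culture. Il2ra was at 2010 ± 539 CPM against 0 (n = 5 and 4; at least 89734-fold), Il22 at 227 ± 163 CPM (at least 10118-fold) and Bub1 at 284 ± 63.3 CPM (at least 12699-fold). Of 15781 genes 3288 rose and 3519 fell by edgeR, and 8072 had an unadjusted p under 0.05. The balance turned with RLE (3713 higher, 3073 lower) and without cells-alone replicate 2 (4654 and 3389), and was 2948 and 3895 with library sizes. The median log2 fold change of all genes was -0.05 with TMM, 0.11 with RLE and -0.17 with library sizes. Genes at 0 in the cells alone also included Lif (at least 10553-fold), Bcat1 (8739), Kif18b (7151), the inhibitory receptor Lilrb4a (6426), Pbk (5762), the opioid precursor Penk (3137) and Il12rb1 (2315). The largest falls were in St8sia6 (-9.43), H2-Ob (-9.30), Patl2 (-8.20), Galnt2l (-8.10), Prg4 (-7.32), Cpne4 (-7.07), Col6a4 (-7.07), Pou6f1 (-6.97), Igf1r (-6.84) and Kcnip2 (-6.52).

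All 20 glycolysis genes rose (20 adjusted over the list alone), with Hk2 at 75.9 ± 34.5 CPM (ratio 10193, exact 95% interval 1829 to 402627, against 2817, 505 to 111319, in the control-macrophage co-culture) and Tpi1 (5.61), Pkm (3.46) and Gapdh (3.42; camera adjusted p = 2.0e-11, and adjusted p = 0.00526 with an estimated correlation). All 33 cell cycle genes rose (33 adjusted over the list alone; camera adjusted p = 2.7e-19, and adjusted p = 0.00394 with an estimated correlation), Mki67 by 8.30 and Birc5 by 10.65. Of 19 activation genes 16 rose and 1 fell (the same adjusted over the list alone; camera adjusted p = 4.5e-07, and adjusted p = 0.0157 with an estimated correlation). Of 18 regulatory T cell genes 16 rose (16 adjusted over the list alone; camera adjusted p = 6.4e-08, and adjusted p = 0.00394 with an estimated correlation), Foxp3 by 2.75. Of 28 cytokine genes 22 rose and 1 fell (23 and 1 adjusted over the list alone; camera adjusted p = 7.0e-09, and adjusted p = 0.00613 with an estimated correlation), with Il17f at least 4495-fold, Il24 at least 2750-fold and Ifng at least 2815-fold higher. Of 21 integrated stress response and serine genes 13 rose and 2 fell (the same adjusted over the list alone; camera adjusted p = 7.7e-05, and adjusted p = 0.00819 with an estimated correlation), with Asns at least 2694-fold higher. Of 18 naive genes 15 fell and 1 rose (the same adjusted over the list alone; camera adjusted p = 6.4e-08, and adjusted p = 0.0157 with an estimated correlation), with Tcf7 (-3.69) and S1pr1 (-3.37) lower.

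Further lists passed camera but not with an estimated correlation. Of 11 T helper 17 genes 8 rose (8 adjusted over the list alone; camera adjusted p = 7.1e-05, and adjusted p = 0.122 with an estimated correlation), with Il17a at least 378-fold and Il1r1 at least 267-fold higher. Of 23 T helper 1 and cytotoxic genes 17 rose and 3 fell (17 and 3 adjusted over the list alone), with Gzmb (13.77) and Il12rb2 (10.20) among them (camera adjusted p = 2.1e-05, and adjusted p = 0.219 with an estimated correlation). Tbx21, the T helper 1 factor, was called (4.14, edgeR adjusted p = 0.0287). Of 18 inhibitory receptor genes 10 rose and 3 fell (10 and 3 adjusted over the list alone; camera adjusted p = 0.0239, and adjusted p = 0.302 with an estimated correlation), with Havcr2 (7.63) and Ctla4 (6.37) higher. Of 36 type I interferon-stimulated genes 25 rose and 3 fell (27 and 3 adjusted over the list alone; camera adjusted p = 3.5e-08, and adjusted p = 0.225 with an estimated correlation), Ifi27l2a by 4.62 and Ifit1 by 3.06. Of 23 interferon gamma response genes 20 rose (20 adjusted over the list alone; camera adjusted p = 1.0e-07, and adjusted p = 0.110 with an estimated correlation). Oxidative phosphorylation had 24 of 45 genes higher (25 adjusted over the list alone; camera adjusted p = 5.8e-06, and adjusted p = 0.122 with an estimated correlation). Cholesterol had 14 of 24 (16 adjusted over the list alone; camera adjusted p = 3.7e-05, and adjusted p = 0.0960 with an estimated correlation). Transforming growth factor beta response genes had 8 of 12 lower and 2 higher (the same adjusted over the list alone; camera adjusted p = 0.00273, and adjusted p = 0.0760 with an estimated correlation). Macrophage markers had 9 of 25 higher (8 adjusted over the list alone; camera adjusted p = 0.00800, and adjusted p = 0.430 with an estimated correlation), with Lyz2 at 23.2 ± 20.05 against 0.0366 ± 0.0732 CPM.

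Camera adjusted p of the other lists against the cells alone were 0.0506 for T helper 2, 0.325 for follicular helper, 0.211 for anergy, 0.0813 for ribosome biogenesis, 0.114 for p53 targets, 0.596 for trafficking, 0.0706 for immediate-early genes and 0.298 for T cell identity. They were 0.453 for B cell, 0.552 for CD8 and NK cell, 0.844 for endocrine and 0.578 for stromal markers and 0.298 for mitochondrially encoded transcripts. Cd44 (1.98), Pdcd1 (1.72) and Izumo1r (1.96) rose, Cd4 (0.18, edgeR adjusted p = 0.438) and Nt5e (0.77, adjusted p = 0.335) did not pass, and neither did Cela1 (1.61, adjusted p = 0.172) or Hba-a1 (0.16, adjusted p = 0.935).

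**Figure D4:**
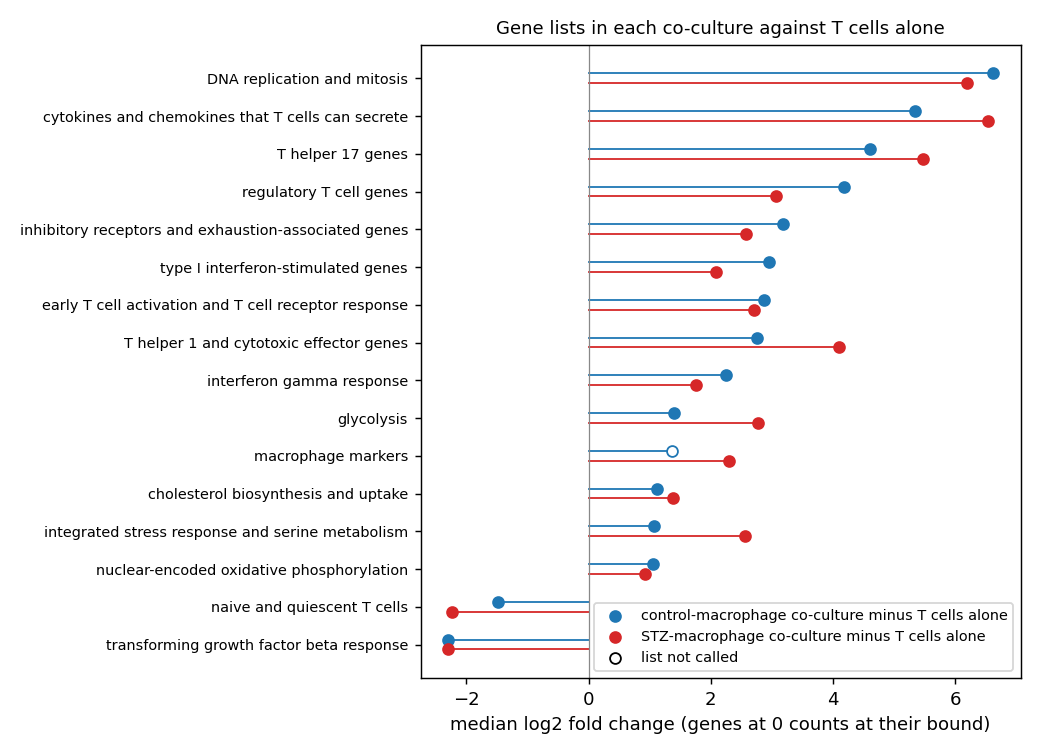
Median log2 fold change of each gene list against the cells alone, in the control-macrophage and the STZ-macrophage co-culture, with genes at 0 in the cells alone set at their bound and open symbols for lists that did not pass camera. The cell cycle list has medians of 6.62 and 6.202, the glycolysis list 1.40 and 2.77, the naive list -1.48 and -2.24 and the transforming growth factor beta list -2.30 in both.

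The co-cultures shared most of their differences from the cells alone. Across genes, which are not independent replicates, the log2 fold changes had r = 0.928 and a covariance of 5.72. In 20 simulations of unchanged groups against the same control libraries the mean was r = 0.550 and the covariance 0.252, with no gene called in both, which leaves a covariance of 5.47. Both co-cultures had 2682 genes higher and 2690 lower, where independent lists of these sizes would share 759 and 773, and 3 genes went opposite ways. With separate cells-alone libraries for each co-culture, in the 6 ways to split 4 libraries evenly, r was 0.638 to 0.8294, the covariance 5.08 to 5.81, and 3874 to 5102 genes were shared. In these splits 4 to 495 genes went opposite ways, the most with cells-alone replicates 1 and 2 set against the control-macrophage co-culture.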

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

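The counts over other splits of the libraries and the tests for a library apart from its group were chosen beforehand. The tests of carry-over, collection days, the cells-alone axis, spread, gene set, single libraries and the chromosome 11 stretch, and the counts of splits for 4 single gene lists, were chosen after the results they explain were seen.

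Of the 126 splits of the 9 co-cultures, 100 were run, the real one included, and 99 could be fitted; the split that follows the days could not. The real split called 51 genes (edgeR) and the highest other one 1 (1 of 99 reached 51). No other split gave as many, although the splits ignored the days, which the groups hold unevenly. With the 9 co-cultures alone the real split called 2698 and the highest other 162 (1 of 99), with the same limit. The real split was also the highest, as 1 of 35, for the control-macrophage co-culture against cells alone (7106 genes, highest other 615). So it was, as 1 of 100 run of 126, for the STZ-macrophage co-culture against cells alone (6807, highest other 1938). Among the 8 splits that part all 4 same-numbered pairs of cells alone and control-macrophage co-culture, the highest other count was 0. If these pairs hold, 8 splits are too few to exclude chance. The other splits place 1 or more pairs on the same side. The number of gene lists passing camera is another matter. As many lists passed in 10 of 99 splits for the co-cultures (13, highest other 16), in 7 of 35 for the control-macrophage co-culture against cells alone (15, highest other 16) and in 8 of 100 for the STZ-macrophage co-culture (16, highest other 18), so chance cannot be excluded for these numbers. The rise of the glycolysis list, with p = 2.1e-04 by camera with an estimated correlation, was matched by 1 of 99 splits, the real one (smallest other p = 0.00704). In the 9 co-cultures alone it was again matched by 1 of 99, so no other split reached it in either fit. By this permutation of the groups, T helper 17 genes (p = 0.0263 by camera with an estimated correlation) were matched by 8 of 99 splits (smallest other p = 0.00629) and by 4 of 99 in the 9 co-cultures alone. Naive genes were matched by 2 of 99 and by 14 of 99, so chance cannot be excluded for either list. Type I interferon genes were matched by the real split alone in both (1 of 99).

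Macrophage carry-over, the uneven days and the difference among the cells alone are candidate explanations of the 51 genes, beside the STZ treatment that the design names. For carry-over, the summed macrophage markers were at 407 ± 146 against 476 ± 150 CPM (difference -69.1, SE 99.4). The 24 genes called higher summed to 4713 ± 1055 against 2318 ± 135 CPM (difference 2395, SE 477). These sums cannot decide carry-over. The marker sum holds genes that B cells also express, and that of the called genes rests on highly expressed ones such as Aldoa. The 18 markers under 1 CPM in the cells alone summed to 78.5 ± 59.5 against 24.8 ± 29.4 CPM (difference 53.8, SE 30.4). Of all 25 markers, 21 had a positive log2 fold change. Against the days, 48 of the 51 genes were called with the same sign in the 5 day 1 co-cultures alone; with all day 1 libraries, cells alone included, 7 genes were called and 3 of them shared, and each of the 51 kept its sign. For the cells-alone axis as the whole cause, the test took the 51 genes. Their median absolute log2 fold change was 1.84 (median SE 0.283) before the axis became a term and 1.57 (median SE 0.309) after. With the term 49 of them were over 2 SE, although only 6 genes were called with these smaller effects and larger SE. Since the 51 were picked by the fit without the axis, these values cannot decide how far the axis is the cause. Over all genes, those with an unadjusted p under 0.05 by edgeR fell from 3604 to 1071. Part of the difference may still belong to carry-over, the axis, GC content (r with the axis 0.385, Spearman) or donors, and the treatment itself stays open as untested against them.

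Far fewer genes were called with the cells alone in the fit (51) than in the 9 co-cultures (2698), by edgeR with the same day term. Against a different set of genes tested, 2604 were called in the co-cultures over the genes of the 13-library fit. A larger spread of the cells alone is a likely source, since their median SD of log2 CPM was 1.74 times that of the co-cultures (0.703 against 0.404). The biological coefficient of variation was 51.4% in the fit of all 13 libraries and 34.5% in that of the 9 co-cultures. A single library may add to the lower count. There were 582 genes called without cells-alone replicate 2, 99 without replicate 4, 79 without replicate 1, 42 without replicate 3 and 51 with all. What made the cells alone differ stays open, and no biological explanation was tested.

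On chromosome 11, 4 neighbouring genes of a 100.2 kb stretch were lower in the day 1 than in the day 2 co-cultures (St6galnac2 from 116675303, Gm11735, BC018473 and St6galnac1 to 116775507; log2 fold changes 4.89, 7.33, 11.41 and 7.93, edgeR adjusted p 1.4e-04, 0.0267, 3.8e-05 and 0.00118). BC018473, an antisense RNA, was at 0.0495 CPM on average (highest 0.164, n = 5) on day 1 and at 143 ± 40.003 (n = 4) on day 2. In the cells alone (n = 4, all of day 1) it was at 7.84 ± 3.59 CPM. In the same order, St6galnac2 was at 1.63 ± 0.859, 54.5 ± 8.70 and 14.4 ± 8.07 CPM. St6galnac1 was at 0.00490, 1.90 and 11.5 CPM, and Gm11735 at 0, 0.348 and 1.17 CPM. The size of the fold changes of these last genes therefore rests on counts at or near 0. The cells alone of the same day expressed these genes, which argues against a stretch missing from every day 1 donor. That 4 of 4 tested genes of the stretch were called tests nothing, since the stretch was drawn around them, and a change confined to it cannot be told apart from a wider segment that differs between donors, because 2 of 37 tested genes within 1 Mb (5.41%, exact 95% interval 0.661 to 18.2, against 3.15% of all genes) leave it open. A donor variant of the T cells remains a hypothesis, as the labels do not give donors per day, and no biological explanation was tested.

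Single libraries stood apart from the rest of their group in 15 of 177 tested sets of values, and chance flags about 1 in 20 sets of normally spread values. Where all other libraries of a group had no count, any count is flagged, so these shares cannot be compared. Cells-alone replicate 2 accounted for 6 of them, in log2 CPM against the lowest and highest of the other cells-alone libraries: Furin 3.32 (1.66 to 1.70), Slamf6 7.70 (8.85 to 9.06), Arl5c 6.98 (7.76 to 7.90), Ifi27l2a 5.50 (6.08 to 6.17), C1qc -2.11 (-4.21, no count) and Tbx21 -0.47 (-4.21, no count). In cells-alone replicate 4, Hk2 stood at -3.59 (-4.21 in the others, no count) and Foxp3 at -0.86 (0.85 to 1.04). Control-macrophage replicate 3 was apart for Ndrg1 at 2.56 (5.09 to 5.52), Cd7 at 4.28 (5.004 to 5.07) and Ins2 at -3.11 (-4.21, no count). Among STZ-macrophage libraries, replicate 4 was apart for Pecam1 at 5.91 (6.31 to 6.43), replicate 1 for Tbx21 at 2.61 (0.22 to 0.53), replicate 3 for Nt5e at 3.98 (4.90 to 5.18) and replicate 2 for its total of 58.8 M counts (33.4 M to 39.0 M). Between the days, the effect of STZ macrophages differed for Arrb1 (difference -4.28, SE 0.48, edgeR adjusted p = 0.0249), at 47.4 and 48.0 CPM in STZ-macrophage replicates 1 and 5 of day 1, 7.55 to 8.70 in replicates 2 to 4, 2.44 to 10.4 in the control-macrophage co-culture and 17.3 to 26.8 in the cells alone.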

How the results depend on the processing

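Alternatives chosen after seeing the data were voom with library weights, the settings without STZ-macrophage replicates 2 and 4 or cells-alone replicate 2, the 9 co-cultures alone with a replicate block, without day, of day 1 only, without each library in turn or for the gene lists, the cells-alone axis as a term and the GC correction. No named gene or gene list reversed its sign past its threshold. Over all called genes this did not hold against the cells alone, and the second deposited table was the largest exception. It kept the sign of 5702 of 6026 tested genes called for the control-macrophage co-culture, and of 5338 of 5714 for the STZ-macrophage co-culture.

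The count for the STZ-macrophage against the control-macrophage co-culture (51, edgeR) moved most. It was 650 with DESeq2 (431 higher, 219 lower; 50 of the 51 shared), 508 with limma voom (47 shared), 477 with the second deposited table and limma (46 shared) and 6422 with voom library weights (51 shared). By edgeR it was 19 without a day term (18 shared), 7 with day 1 only (3 shared), 2698 with the co-cultures alone (51 shared), 582 without cells-alone replicate 2 (51 shared), 158 with the co-cultures alone and no day term (26 shared), 1531 with the day 1 co-cultures (48 shared) and 6 with the cells-alone axis as a term (5 shared). It was 0 by edgeR with the replicate block (1368 genes at an unadjusted p under 0.05), without STZ-macrophage replicates 2 and 4 (1820) and with the co-cultures alone and a replicate block (1640); other tools were not run in these settings. Leaving out 1 co-culture at a time gave 0 (without control-macrophage replicate 4, STZ-macrophage replicate 1 or 5; 1555, 2061 and 2522 unadjusted) to 87 (without control-macrophage replicate 3), with 4 and 6 without control-macrophage replicates 1 and 2 and 8, 24 and 5 without STZ-macrophage replicates 2, 3 and 4. In each of these settings every tested one of the 51 genes kept its sign. That is partly built in, since the fit of all libraries picked the 51 and the settings reuse most of those libraries. Total counts stayed within 1.5-fold, from 41 to 64, with RLE, library sizes, both filters, a minimum fold and the GC correction. The balance of higher and lower genes moved more, as given above for RLE and library sizes. Fewer samples or degrees of freedom lower the power of the replicate block and the smaller sets by construction. Sample number does not account for the 7 genes of day 1, since its co-cultures alone called 1531. Otherwise the cause was not tested. For the axis term, effects and SE are given above.

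Over the 9 co-cultures alone the count of 2698 ranged from 585 (without STZ-macrophage replicate 1) to 3375 (without control-macrophage replicate 2), with 1189 and 1138 without control-macrophage replicates 1 and 4 and 1667, 963 and 866 without STZ-macrophage replicates 3, 4 and 5. Against the cells alone the control-macrophage count (7106) was 4814 to 8920 over all alternatives, 5745 to 7760 leaving out 1 library and 5887 with the replicate block. The STZ-macrophage count (6807) was 4810 to 9665 over the other alternatives, 5137 to 8043 leaving out 1 library and 3476 with the replicate block (1938 higher, 1538 lower; 3448 shared). The replicate block ties libraries that the data may pair only between cells alone and control-macrophage co-culture. Correlations of same-numbered pairs were -0.202 to 0.474 between the co-cultures, with 1 of 4 best with its own number, and -0.415 to 0.331 between cells alone and STZ-macrophage co-culture, also 1 of 4. The day difference, 1 gene by edgeR and with RLE, was 404 genes with DESeq2; the cause was not tested.

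Gene lists called moved with the assumed correlation. With an estimated correlation, 1 list passed between the co-cultures (13 with the preset), 8 for the control-macrophage co-culture (15) and 7 for the STZ-macrophage co-culture against cells alone (16), and fry called 25 in the last. Leaving out 1 library gave 12 to 14, 15 to 17 and 16 to 18 lists. Of 13 lists called between the co-cultures, 208 of 234 alternative tests kept the call and 26 lost it, and only glycolysis kept it in all of these; with the GC correction and an estimated correlation together its adjusted p was 0.198. Trafficking lost it most often, with adjusted p up to 0.149.

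Among named genes, 27 were called between the co-cultures, and 380 of 756 alternative tests kept the call and 376 lost it with the same sign, none being called in all settings. Of 98 not called, 279 of 2704 tests called them. Against the cells alone the named genes were firmer, with 1627 of 1650 calls kept for the control-macrophage co-culture (75 of 83 genes in all settings) and 1741 of 1756 for the STZ-macrophage co-culture (73 of 80). Totals ran from 17.3 M to 61.3 M counts, and in simulations at these depths the edgeR test recovered 34.0% of 4-fold and 6.12% of 2-fold rises between the co-cultures, so smaller changes are missed.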

Other observations

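The collection days and a list of oxygen-sensing genes lie outside the comparisons of the report. The tests between the days and the further values of the oxygen-sensing list with the axis or GC correction were chosen after results were seen, and the test of that list was written before its values were seen but after the genes called.

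Between day 2 and day 1, within co-culture groups, 332 genes were higher and 165 lower (497 by edgeR, 4554 at an unadjusted p under 0.05). By camera the activation list was higher on day 2 (17 of 19 genes with a positive log2 fold change, median 0.84, adjusted p = 0.00122; 0.326 with an estimated correlation), as were T helper 1 and cytotoxic genes (21 of 23, adjusted p = 0.00122; 0.485) and macrophage markers (24 of 25, adjusted p = 0.00122; 0.485). Ribosome biogenesis (7 of 25 genes called, adjusted p = 0.00144; 0.485), cytokines (4 of 28 called, adjusted p = 0.00164; 0.326) and inhibitory receptors (adjusted p = 0.0406; 0.485) passed camera as well, and none of these lists passed with an estimated correlation. Across genes, which are not independent replicates, the day difference had r = -0.790 with the loadings of the cells-alone axis. The second deposited table gave the STZ-macrophage against control-macrophage fold changes r = 0.792 with the same loadings. The days hold different libraries of both co-cultures and no cells alone on day 2, so donors, handling and day are 1 variable here.

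With the cells-alone axis as a term, camera also passed T helper 1 and cytotoxic genes (adjusted p = 0.00383), inhibitory receptors (0.0468), oxidative phosphorylation (0.00169, lower) and mitochondrially encoded transcripts (4.1e-07, higher) between the co-cultures, but none of them with an estimated correlation (0.352, 0.236, 0.328 and 0.262). After the GC correction, p53 targets (0.0746), immediate-early genes (0.0717) and trafficking (0.149) no longer passed and mitochondrially encoded transcripts did (4.1e-05, higher; 0.356 with an estimated correlation).

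Ndrg1, Hk2, Slc2a1, Slc2a3 and P4ha1 among the genes higher with STZ macrophages are known targets of the oxygen-sensing factor HIF, so the hypothesis was that a wider set of its targets was higher. A list of 28 other targets, 25 of them tested, was written without called genes and without members of the glycolysis list. Its median log2 fold change was 1.20, with 21 of 25 positive. By camera with an estimated correlation the list was higher at an unadjusted p of 0.0122 (5.8e-09 with the preset correlation). That p covers this list alone, whereas the fixed lists were adjusted over all lists of the comparison. It therefore cannot be set beside their adjusted p. The oxygen-sensing list was also not tested over the other splits of the libraries. None of its genes was called by edgeR with 13 libraries, where 3604 of all genes had an unadjusted p under 0.05, and 15 of 25 were higher and none lower in the 9 co-cultures alone. Bnip3 was at 1.57, Fam162a at 1.87 (adjusted p = 0.00344 in the 9 co-cultures), Plod2 at 2.47, Gys1 at 1.31 (0.00450), Ak4 at 3.20 and Mif at 1.75. With the cells-alone axis as a term the median was 0.68 (unadjusted camera p = 0.0163 with an estimated correlation), and after the GC correction 0.81 (unadjusted camera p = 0.0155). Higher HIF activity in T cells beside macrophages of STZ-treated donors remains a hypothesis. These data cannot separate it from less oxygen in denser cultures, and cell densities are not given in the sources used here.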
